A study of Thermothelomyces thermophilus ATCC 42464 with 3 samples.

How the data were processed

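Messenger RNA levels were measured by RNA sequencing in mycelium of Thermothelomyces thermophilus ATCC 42464 (formerly Myceliophthora thermophila), a thermophilic filamentous fungus that degrades plant biomass. Per the labels' protocols, cultures grew for 16 h at 45 °C on 2% glucose and were moved for 4 h to 2% Avicel, a microcrystalline cellulose. There were 3 libraries. 1 library carried the genotype label of a MYCTH_90344 deletion mutant and 2 were labelled wild type (WT). The study's title describes MYCTH_90344 as a transcription factor that acts on cellulase genes. The labels did not say whether the WT libraries came from separate cultures, so p-values measured only the spread between these libraries, which may be technical.

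The authors deposited 1 table with read counts and FPKM for 9292 genes in each library. Per the file headers, the counts were raw reads per gene and the FPKM values were normalised for gene length and library size. Per the submitters' processing notes, TopHat2 2.0.8b and HTSeq 0.5.4p2 were used. Their settings, the genome build, the annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes may share reads. The FPKM deposited by the authors were the counts times 1 factor per library over a gene length common to the libraries (largest relative deviation 2.90e-08), so they held no information on gene changes beyond the counts. All 9292 locus tags matched the gene table of assembly ASM22609v1, which listed 9097 protein-coding genes, 194 tRNA genes or tRNA pseudogenes and 1 other pseudogene. That table was used for gene names, gene type and gene order, and no coordinates are given because the authors' build was not stated. No column of other samples was present.

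Library totals were 20774092 counts for the library labelled deletion, 21827636 for WT replicate 1 and 20166880 for WT replicate 2. A floor of 3 counts corresponded to 0.144, 0.137 and 0.149 CPM (counts per 1000000 counts) respectively. Intervals for shares of counts are 95% Wilson intervals and cover counting error only.

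Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (8340 tested, 952 left out), libraries were scaled by TMM, and glmQLFit and glmQLFTest compared the library labelled deletion with WT. Unless another test is named, adjusted p-values are Benjamini-Hochberg values from this edgeR quasi-likelihood test, with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size over the square root of F. With 1 library labelled deletion, the spread came from the WT pair alone (1 residual degree of freedom per gene, moderated across genes with 30.0 prior degrees of freedom), and that library was assumed to vary like WT. A second, untested summary counted genes whose log2 fold change (prior count 2) was at least 1 in size, whose level lay outside both WT values and whose higher group reached 5 CPM. The 2 WT libraries differed by more than sampling noise (chi-square 43615 on 8395 degrees of freedom) and were kept as 2 libraries.

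29 gene lists were fixed before the data were examined, defined by product descriptions and by locus tags. The gene table held no descriptions and only 6 symbols other than the locus tag, so 26 lists, among them secretory pathway, stress, ribosome and conidia markers, had no members and gave no result. The lists of cellulases (5 genes), beta-glucosidase families (2 genes) and cellobiose dehydrogenase (1 gene) kept the members written by locus tag. Their enzyme classes, and the names cbh-1, cbh-2, clr-2, xyr-1 and cre-1, come from published work on this species, not from the files. The list of 5 was tested with camera (preset correlation 0.01) and its median compared with 10000 random lists matched on mean expression. The other 2 lists had fewer than 3 members and are given gene by gene. No locus was matched to hac-1, and it is not reported here.

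The rule for named genes took MYCTH_90344, the gene named in the deletion label, with 3 neighbours on each side, the list members, and the 12 largest rises and 12 largest falls among genes past the test, outside both WT values and at 10 CPM or more in the higher group, with at most 5 loci of unknown function named. The gene table's 6 symbols and the regulators clr-2, xyr-1 and cre-1 were added after the table was seen and before their values were. Loci named at the ends of gene runs were chosen after their values were seen.

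The fit was tested on simulated counts for the real genes with 200 changed genes. These were drawn from genes with a mean of at least 10 CPM, and every gene was given the same spread. Recovery of genes at lower levels was not tested. It recovered 100 of 100 genes changed by 2 and 100 of 100 changed by 1 on the log2 scale, and 6.54% of its calls were unchanged genes. In a second simulation no gene changed, but the single library varied with a biological coefficient of variation (BCV) of 0.2, against 0.0484 in the WT pair. 2699 of 8268 genes then passed the test and 10 passed the size rule.

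Alternatives were other scalings (RLE, upper quartile, library totals, totals without the 20 most abundant genes), other filters, DESeq2 1.42.0, limma-voom and limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), the edgeR likelihood ratio test, robust=TRUE and legacy=FALSE, an adjusted p under 0.01, glmTreat with a minimum fold of 1.5, and leaving out each WT library. A test with a BCV of 0.2 set for every gene, added after the data were seen, was an edgeR likelihood ratio test. Figures were drawn with matplotlib 3.10.9.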

Results

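The data comprised 3 libraries of mycelium moved from glucose to Avicel for 4 h, with 20166880 to 21827636 reads counted on genes in each. 2 libraries were WT and 1 was labelled as the MYCTH_90344 deletion mutant. At this depth 8672 to 8734 of the 9292 genes had at least 1 count. The WT libraries correlated across genes with a Spearman's rho of 0.997 (genes are not independent replicates), and no gene passed the 2-fold size rule between them. Between the library labelled deletion and each WT library rho was 0.948 and 0.950, and 868 and 817 genes passed that rule. WT values are given as mean ± SD (n = 2). The library labelled deletion had no replicate.

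The labelled gene itself was examined first. MYCTH_90344 was not absent from the library labelled deletion but rose there, from 10.8 ± 1.16 CPM (SD, n = 2) in WT to 334 CPM. The log2 fold change was 4.95 (SE 0.09), a 30.9-fold rise (edgeR adjusted p = 3.14e-30). This rested on 6978 reads, against 217 and 236 in the WT libraries. The deposited FPKM, which are scaled counts and so no separate evidence, gave a log2 change of 4.94. This level goes against the deletion label, so the library is called by its label throughout, and every direction below is a direction in that library. The 6 genes next to MYCTH_90344 in assembly ASM22609v1 did not share the rise. 5 of them did not pass the test, with log2 fold changes between -0.09 in MYCTH_2132441 and 0.12 in MYCTH_2297953. MYCTH_2297957 and MYCTH_2297964, its immediate neighbours, were at 36.0 and 9.10 CPM, against 36.3 ± 2.21 and 8.40 ± 0.706 CPM (SD, n = 2) in WT. MYCTH_2297971 had a log2 fold change of 0.05. MYCTH_2297954 fell, from 2.39 ± 0.0885 CPM (SD, n = 2) to 1.10 CPM (edgeR adjusted p = 0.0361), but did not pass with DESeq2 (adjusted p = 0.229).

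The second comparison addressed cellulase genes, on which MYCTH_90344 acts per the study's title. The title names cbh-1, which is among the listed genes, and hac-1, which is not reported here. The other listed genes were chosen for this report and are not named in the title. In the library labelled deletion, in which MYCTH_90344 itself was raised, each of the 5 listed cellulase genes fell, by 2.46- to 3.84-fold. cbh-1 (MYCTH_109566), a cellobiohydrolase, which releases cellobiose from cellulose chain ends, fell from 14808 ± 48.0 CPM (SD, n = 2) to 3855 CPM, a log2 fold change of -1.94 (SE 0.08, edgeR adjusted p = 2.15e-20). cbh-1 had taken 1.48% ± 0.00717 (SD, n = 2) of all counts in WT and took 0.387% (95% Wilson interval 0.385 to 0.390%) in the library labelled deletion. cbh-2 (MYCTH_66729), a cellobiohydrolase of another family, fell from 7954 ± 227 to 3229 CPM. The endoglucanases, which cut within cellulose chains, fell from 7552 ± 31.1 to 2853 CPM for MYCTH_86753, from 999 ± 48.4 to 260 CPM for MYCTH_111372 and from 846 ± 76.6 to 269 CPM for MYCTH_76901.

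Enzymes that act beside the cellulases fell as well. The beta-glucosidases, which split cellobiose into glucose, fell from 28.7 ± 2.27 CPM (SD, n = 2) to 4.79 CPM for MYCTH_66804 and from 1708 ± 16.2 to 592 CPM, or 2.89-fold, for MYCTH_115968. cbdA (MYCTH_111388), a cellobiose dehydrogenase that oxidises cellobiose, fell 4.98-fold, from 3757 ± 42.2 to 754 CPM. Together these 8 genes held 3.76% ± 0.0360 (SD, n = 2) of all counts in WT and 1.19% (95% Wilson interval 1.18 to 1.19%) in the library labelled deletion.

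All 5 cellulases passed the test downwards, adjusted over all genes and adjusted over the list alone, as did both beta-glucosidases and the cellobiose dehydrogenase. The median log2 fold change of the cellulase list was -1.65, a level reached by 0.510% of 10000 random lists matched on expression. Genes of the random lists were drawn independently. The share therefore does not allow for cellulase genes that change together, and it does not measure variation between cultures. The list differed from other genes with a preset correlation (camera p = 2.00e-07). The call was lost when camera estimated the correlation (p = 0.119). That estimate was -0.2, so no positive correlation was found, and the test then has 1 degree of freedom. With a BCV of 0.2 assumed for every gene, each of the 8 genes still passed. Adjusted p in this edgeR likelihood ratio test lay between 5.99e-08 for MYCTH_66804 and 0.00738 for MYCTH_66729.

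**Figure D1:**
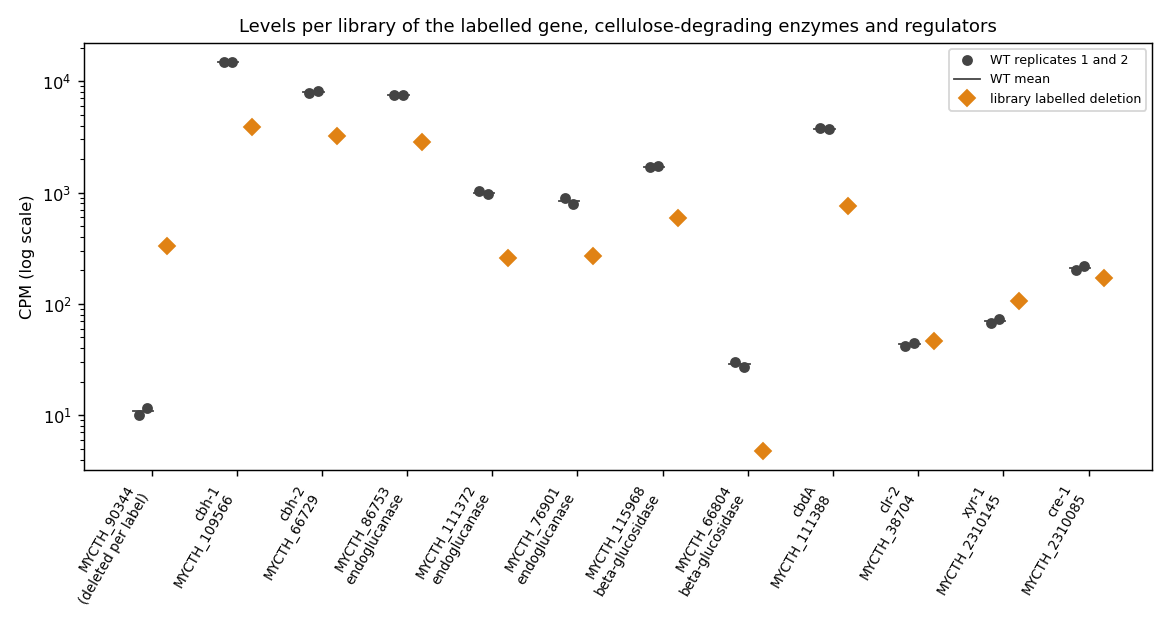
CPM per library (log axis) of MYCTH_90344, 8 genes of cellulose degradation and 3 regulators. Circles are WT replicates 1 and 2, short lines their mean, and diamonds the library labelled deletion (n = 1). MYCTH_90344 lies 30.9-fold above the WT mean and each cellulose-degrading enzyme below both WT values.

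The 3 known regulators of cellulase genes that were examined differed by at most 1.51-fold. clr-2 (MYCTH_38704), an activator of cellulase genes, was at 43.3 ± 2.41 CPM (SD, n = 2) in WT and 46.3 CPM in the library labelled deletion and did not pass the test (edgeR adjusted p = 0.429). xyr-1 (MYCTH_2310145), a regulator of xylan and cellulose degradation, rose 1.51-fold, from 70.5 ± 4.12 to 106 CPM. cre-1 (MYCTH_2310085), which mediates carbon catabolite repression, fell 1.24-fold, from 210 ± 13.7 to 169 CPM. The xyr-1 and cre-1 calls ended with a BCV of 0.2 (edgeR likelihood ratio test, adjusted p = 0.321 and 0.692).

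Other genes with a symbol showed no common direction. ganA (MYCTH_43163), an arabinogalactan-degrading galactanase, fell 2.41-fold, from 24.2 ± 0.799 CPM (SD, n = 2) to 10.1 CPM. gla1 (MYCTH_72393), a starch-degrading glucoamylase, fell 2.04-fold, from 12.6 and 11.4 CPM in the WT libraries to 5.89 CPM. cat1 (MYCTH_80916) rose 1.27-fold, from 120.0 ± 6.92 to 153 CPM. phy1 (MYCTH_104551), a phytase, was at 33.9 ± 0.404 CPM in WT and 35.7 CPM in the library labelled deletion and did not pass the test (edgeR adjusted p = 0.569). lcc1 (MYCTH_51627), a laccase, had 0 reads in the library labelled deletion, which allows a level of up to 0.144 CPM, and 1 and 3 reads in the WT libraries. The gla1 and cat1 calls ended with a BCV of 0.2 (edgeR likelihood ratio test, adjusted p = 0.0686 and 0.636).

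Changes across the transcriptome were counted next, with directions relative to the TMM scaling, which centres most genes near no change. Of 8340 tested genes, 499 rose and 555 fell by at least 2-fold and passed the edgeR quasi-likelihood test. The 2-fold minimum was joined to the test after the data were seen. The test is against no change, so its adjusted p does not cover the 2-fold size. Without a minimum fold, 2343 genes rose and 2300 fell, 55.7% of those tested, and 77.3% of these changed by less than 2-fold. With upper quartile scaling 2467 rose and 2087 fell, so the balance of directions depends on the scaling. By the size rule, without a test, 395 genes were higher and 424 lower, and all 819 passed the test. Among the 100 genes with the highest mean level, 10 rose and 14 fell by at least 2-fold. The low spread of the WT pair (BCV 0.0484) set the count of small changes: with a BCV of 0.2, 1017 genes passed, of which 995 were among the calls above.

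**Figure D2:**
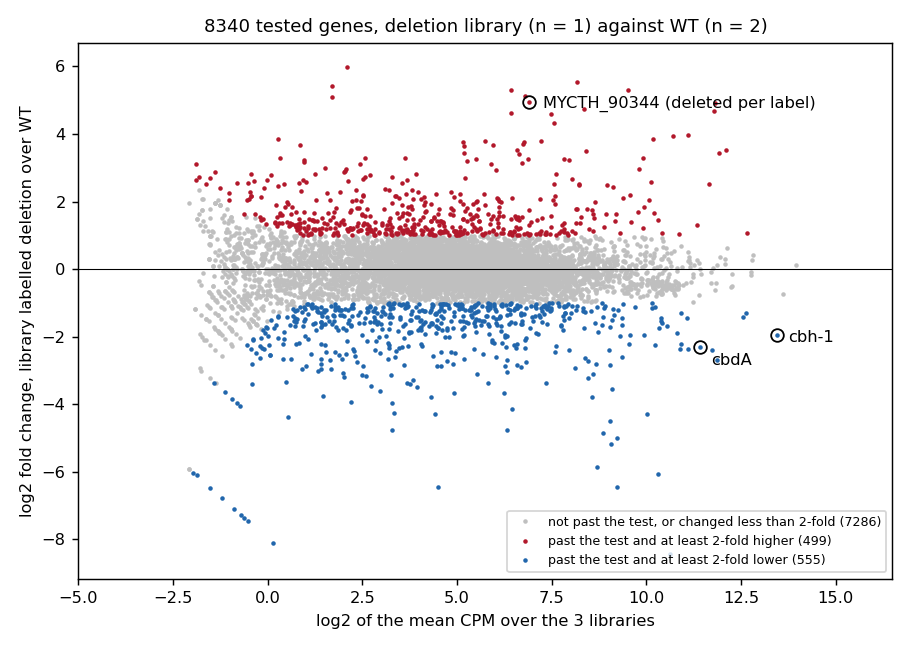
Log2 fold change of the library labelled deletion (n = 1) over WT (n = 2) against the log2 of the mean CPM, 1 point per tested gene. Red and blue points are the 499 genes that rose and the 555 that fell by at least 2-fold and passed the test; the diagonal of points at the lower left holds genes with 0 counts in the library labelled deletion, whose fitted fold depends on the prior count.

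The largest changes lay outside the 8 listed genes of cellulose degradation. The gene table gave no class for any locus and held only 6 symbols, so the lack of a symbol says nothing about a locus. Of the 12 largest rises among genes at 10 CPM or more in the higher group, MYCTH_90344 ranked sixth and the other 11 loci had no symbol or listed function. MYCTH_2118002 ranked first in the fit, rising from 0.191 ± 0.00915 CPM (SD, n = 2) to 12.5 CPM, or 63.2-fold, on few WT reads. With log2(FPKM + 1) its log2 change was 3.11, the smallest of the 12, against 5.98 in the fit and 6.02 with DESeq2. The added 1 exceeds its WT mean of 0.136 FPKM, which shrinks the value of 3.11. MYCTH_2313641 followed, rising 46.8-fold from 17.8 ± 2.24 to 831 CPM. None of the 12 largest falls had a symbol. MYCTH_115957 fell from 2357 ± 98.6 to 6.75 CPM, or 349-fold, and MYCTH_50128 from 890 ± 69.7 to 10.2 CPM, or 87.6-fold. Both lie in 1 stretch of 12 neighbouring genes that held 9 of the 12 largest falls. The edgeR adjusted p of these 4 loci lay between 5.70e-32 for MYCTH_115957 and 2.69e-15 for MYCTH_2118002.

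**Figure D3:**
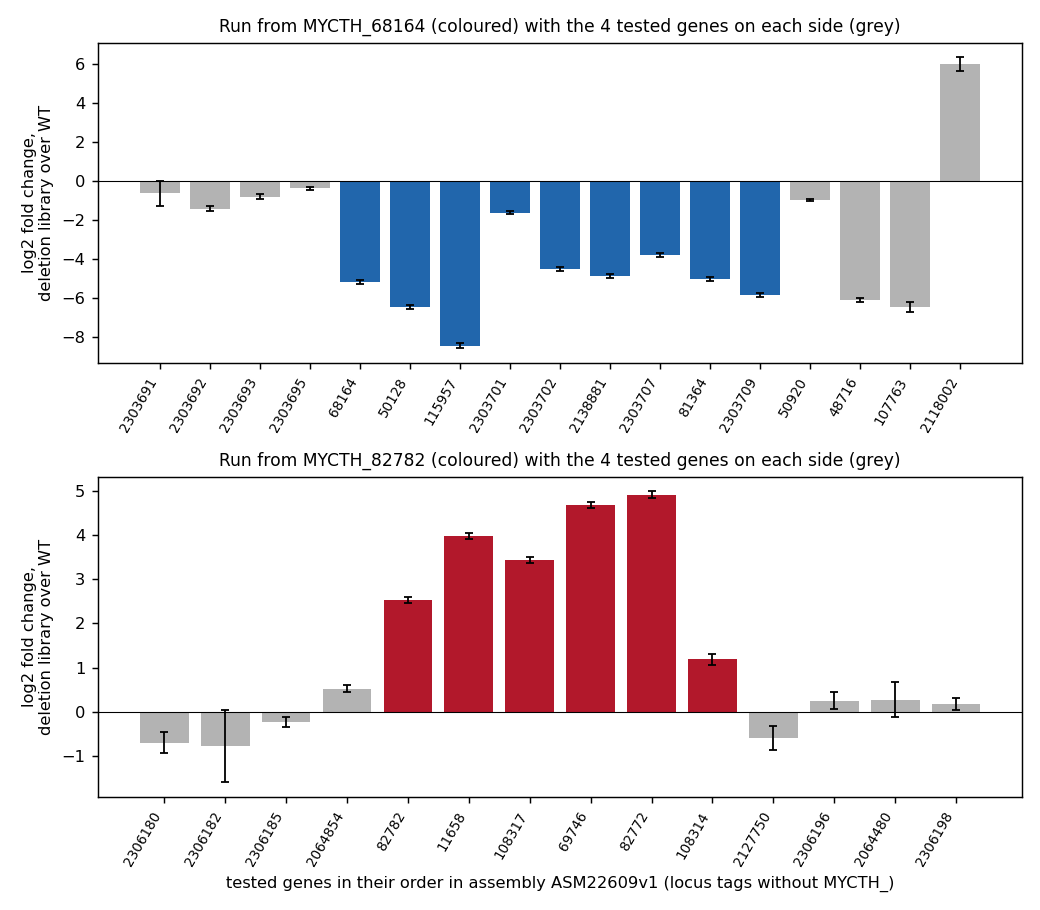
Log2 fold change of the library labelled deletion (n = 1) over WT (n = 2), with error bars of 1 SE, for tested genes in their order along assembly ASM22609v1. The upper panel holds the stretch with the largest falls, from MYCTH_68164 to MYCTH_107763, and the lower panel a run of 6 genes that rose, from MYCTH_82782 to MYCTH_108314; grey bars are the genes beside each run.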

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

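The count of genes past the test and changed by at least 2-fold lay between 650 (genes with a mean of at least 10 CPM) and 1149 (likelihood ratio test) over the alternatives, against 1054, and the count without a minimum fold depended on the assumed spread. Against 4643 genes past the test (2343 higher, 2300 lower), DESeq2 gave 3117, of which 1459 were higher, and 3115 of its calls were among the 4643. glmTreat with a minimum fold of 1.5 gave 1278 (622 higher, 656 lower). Alternatives chosen after the data were seen gave 1017 (518 higher, 499 lower) with a BCV of 0.2, and 1054 (499 higher, 555 lower) with a log2 change of at least 1 as well. By construction, glmTreat has a stricter null and the count of 1054 an added minimum fold. The BCV of 0.2 has a larger spread and a likelihood ratio test. For DESeq2 the cause was not tested. Counts under the other scalings, filters and tools stayed within 1.5 times, between 3792 (adjusted p under 0.01) and 4807 (likelihood ratio test). The size rule gave 213 genes (101 higher, 112 lower) at a log2 change of at least 2, against 819 at 1. Leaving out a WT library gave 817 to 868 genes by that rule (395 to 436 higher, 422 to 432 lower), a log2 fold change of MYCTH_90344 of 4.85 to 5.06 and a cellulase median of -1.74 to -1.55. These are values without a test, since no residual degree of freedom remains, and the edgeR counts have no such values. The library labelled deletion cannot be left out. The cellulase median was -1.80 over all 8 cellulose-degrading genes. The cellulase set test lost its call with an estimated correlation (p = 0.119), which leaves 1 degree of freedom, and kept it in the other alternatives, with p between 7.15e-13 and 0.0171 (fry, which tests the list without comparing it with other genes). Among 45 named genes, no direction of a gene past the test changed, 1 call was lost with DESeq2 (MYCTH_2297954, adjusted p = 0.229), and 33 of 38 calls held with a BCV of 0.2. Without a test, log2(FPKM + 1) moved 23 of the 45 by more than the spread of the WT pair, among them MYCTH_2118002 (from 5.98 to 3.11) and MYCTH_107763 (from -6.45 to -4.66). That spread was small for some genes, so small shifts count as moved, such as MYCTH_109566 (from -1.94 to -1.95). Leaving out WT replicate 1 or 2 moved 10 or 2, and the largest log2 shift in size was 0.14. Counting depth limited genes near 3 counts, or 0.149 CPM, such as lcc1. No paired analysis was possible because the labels give no pairing and only 1 library was labelled deletion.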

Other observations

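The tests of explanations and of gene runs in this part were chosen after the results were seen. A small part of the 1054 genes past the test and changed by at least 2-fold, 57 genes, lay in 12 runs of 4 or more neighbouring tested genes that changed in 1 direction, in the gene order of assembly ASM22609v1; the others lay outside such runs. The run with the largest median fall had 9 genes from MYCTH_68164 to MYCTH_2303709, which fell by 3.08- to 349-fold. They went from 0.766% ± 0.00475 (SD, n = 2) of all counts in WT to 0.0219% (95% Wilson interval 0.0213 to 0.0226%) in the library labelled deletion. The next gene, MYCTH_50920, fell less (log2 fold change -0.97), and the 2 after it, MYCTH_48716 and MYCTH_107763, fell 67.3- and 87.2-fold, so that 11 of 12 neighbours fell by at least 2-fold. The gene just beyond, MYCTH_2118002, rose, on few WT reads (log2 fold change 5.98, and 3.11 with log2(FPKM + 1)). Genes just before the run also fell, but by less than any gene of the run. Their log2 fold changes were -0.37 in MYCTH_2303695, -0.80 in MYCTH_2303693 and -1.41 in MYCTH_2303692.

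The run with the largest median rise had 6 genes from MYCTH_82782 to MYCTH_108314. 5 of them were abundant and went from 336 to 1257 CPM in WT to 5836 to 10131 CPM, rises of 5.73- to 30.1-fold, and MYCTH_108314 rose 2.27-fold to 32.3 CPM. The 6 genes held 0.327% ± 0.00770 (SD, n = 2) of all counts in WT and 4.30% (95% Wilson interval 4.30 to 4.31%) in the library labelled deletion, more than the 8 cellulose-degrading genes held in WT (3.76%). Neither run has a named gene in the table used. 5 genes went from at least 10 CPM in both WT libraries to under 1 CPM, and 1 gene went the opposite way.

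Chance and changes in the DNA were weighed as explanations of the runs. Shuffling the changes within chromosomes gave at most 16 genes in runs, against 57 observed (permutation p = 0.0001, the smallest that 10000 permutations can give), which argues against chance placement. Loss of the DNA of the whole falling run is argued against by its genes' levels, a median of 3.11% of WT with a range of 0.287 to 32.5%. Carried-over reads would leave 1 low ratio for all of its genes. The lowest ratio of any abundant gene was that of a gene of this run, so loss of a part of the run stays open. A single gain in copy number of the rising run is argued against by fold changes that range over 2.39 on the log2 scale among its 5 abundant genes (largest SE 0.07). Shared regulation of the genes of a run, by the genotype, the raised MYCTH_90344 level or the culture, was not tested.

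The rise of MYCTH_90344 in the library labelled deletion is the result most in need of a second look. A change of the whole locus is argued against by the 6 neighbours, of which the highest log2 fold change was 0.12. A WT culture under a wrong label stays open. Leaving MYCTH_90344 out, at least 816 genes passed the size rule against each WT library and 0 between the WT libraries, but that pair may come from 1 culture, so a separate WT culture cannot be told apart from a mutant by this count. Also open is transcription of a part of the gene left at the locus, or of a construct that carries the gene, as in an overexpression strain: the 6978 reads are summed over the gene and these cannot be told apart, because no coverage along the gene was used. The fall of the 8 cellulose-degrading genes therefore may go with loss or gain of MYCTH_90344, or with the culture.

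The large number of calls was weighed against technical differences. Library size is argued against by totals that differed little (ratio 0.989 of the library labelled deletion to the WT mean). A few dominant genes are argued against by similar counts of genes past the test and changed at least 2-fold. Scaling by library totals alone gave 1064, and totals that left out the 20 most abundant genes gave 1066. The main fit gave 1054, but its TMM scaling already limits the weight of such genes. The spread of separate cultures, which the WT pair may understate, stays open and cannot be told apart from the genotype with 1 library; 1017 genes passed with an assumed BCV of 0.2.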
